A study of Homo sapiens with 6 samples.

How the data were processed

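RNA sequencing of C28/I2 cells at day 2 after transfection gave 6 libraries, 3 with the piR_019914 mimic and 3 with a negative control mimic. Groups were taken from the sample titles and the treatment label. The cell line field of all 6 samples names the negative control, which goes against the titles and the treatment of the 3 mimic samples. Per the labels' protocols the mimics were delivered with a lipid transfection reagent, RNA was purified with spin columns and libraries were made with a SMARTER mRNA kit.

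The authors deposited 1 table of 44286 features, of which 31213 carry a gene symbol, with estimated counts and FPKM per library, per the file headers. FPKM values, fragments per kilobase of transcript scaled to library size, are as the authors deposited them and total 221703 to 243253 per library. The aligner, the counter and their versions are not given in the sources used here. Per the submitters' processing notes the genome builds are GRCm38, a mouse build, and T2T-CHM13. All 41714 features with an identifier in GENCODE v29 lie on the same chromosome there, and 84.9% have the same start or end, so coordinates printed here are those of the table and are read as GRCh38. The table holds 24 further value columns for 12 libraries that are not samples here, and none of them was used.

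The deposited estimated counts are whole numbers already, so the rounding that estimated counts need changed none of them. More features sit at exactly 4 counts than at 3 or 5 in each library, and the variance between replicates was 4.22 and 4.50 times the mean at 20 to 40 counts in the control and mimic groups. About 4 counts per sequenced fragment would give both, and spread between replicates would add to the variance, so the number of counts per fragment stays unsettled. If it is over 1, library totals of about 56390500 to 60897500 counts overstate the depth, and counting intervals, which cover counting error only, are too narrow. A share of values equal between libraries of at most 0.483% among features over 50 counts gave no sign of a library deposited under 2 names.

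The fixed design named limma on log2(FPKM + 1) unless the table held raw counts, in which case edgeR was to be used. The estimated counts were taken to meet that condition. The main test is therefore edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the estimated counts, with filterByExpr, TMM scaling, no covariate and Benjamini-Hochberg adjustment over 22086 tested features, two-sided, at an adjusted p of 0.05. Standard errors are the absolute log2 fold change over the square root of its F statistic. CPM values are the counts divided by the TMM-scaled library size, on the usual CPM scale. Log2 CPM for list tests used a prior count of 2.

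Before the data were examined 37 gene lists were fixed, and 36 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Genes were named by a rule fixed at the same time. It took the 10 largest rises and 10 largest falls among called genes with a symbol, no overlap between the groups and at least 5 CPM in a group, up to 4 members with the smallest p of each described list, and 14 genes of cartilage, ferroptosis and small RNA function. CMPK2, LIPA, IRF7, CXCL10, CXCL11, TVP23C, CDRT4, PARP9, PARP14 and the fat cell transcripts are outside that rule and were named after their values were seen. ADH1B, with 2 counts in 1 group, is given as a ratio with a 95% exact binomial interval.

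Counts for 22086 features were simulated from the means and dispersions of this comparison. The changed genes were drawn from features with a mean of 5 CPM or more, so recovery at lower levels was not simulated. Of these, edgeR found 57 of 100 genes changed by 0.5 log2 and 92 of 100 changed by 1 log2. No change had been simulated for 3.87% of its calls. With no change simulated edgeR called 6 features. Camera called the 1 list that had been shifted, and none when no list had been. Features were simulated independently of one another, so this does not test camera on lists whose members vary together. The GC and length offset took an added GC trend from a rank correlation of 0.503 to -0.0056.

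Alternatives planned before the data were examined covered DESeq2 1.42.0 and its size factors, library totals, filters, limma with and without a trend, robust moderation and library weights, quantile normalization, pseudocounts for FPKM, the replicate number as a block, each library left out, other thresholds and feature sets, camera with an estimated correlation and fry. Alternatives added afterwards were limma on log2 CPM, an offset for GC content and length, and the counts divided by 4. A fit without control libraries 2 and 3 was added then as well. Limma on log2(FPKM + 1), named in the fixed design for a table without raw counts, was run as an alternative too. GC content, length and 3' UTRs came from GENCODE v29 transcripts. GC content and length were known for 96.5% of tested features.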

Results

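The series measured gene expression by RNA sequencing in C28/I2 cells, an established line of human chondrocytes, the cells that make cartilage. Cells were transfected with a synthetic mimic of the PIWI-interacting RNA piR_019914 or with a negative control mimic. PIWI-interacting RNAs are small RNAs best known from the germ line, where they guide PIWI proteins. RNA was taken on day 2. Each group held 3 libraries, and the comparison asks which transcripts differ in level when the cells receive the piR_019914 mimic in place of its control. Estimated counts per library totalled between about 56390500 and 60897500. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. Correlations of log2 levels were 0.970 to 0.974 between libraries of the same group and 0.968 to 0.971 between groups. The first principal component held 25% of the variance and separated the groups.

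Interferon-stimulated genes, which cells switch on in an antiviral response, rose together with the piR_019914 mimic. Of 38 tested members of the list, 35 rose, none fell and 3 did not pass the edgeR test, with a median log2 fold change of 1.68, a 3.20-fold increase. IFIT1, an antiviral protein that binds viral RNA, rose 8.31-fold, from 28 ± 4.49 to 233 ± 40.2 CPM (counts scaled to library size; SD, n = 3 libraries per group; edgeR adjusted p = 6.0e-07). Genes that act in mitosis were lower, with 20 of 34 tested members fallen and a median log2 fold change of -0.19. Most changes outside the interferon list were small. Over all features, 1557 of 22086 tested differed at an adjusted p under 0.05, of which 711 were higher and 846 lower with the mimic. The median log2 fold change was 0.41 among the higher features and -0.30 among the lower ones. An absolute log2 fold change of 1 or more was reached by 142 of them, 114 higher and 28 lower. Limma on log2(FPKM + 1), which differs in unit, test and scaling, gave another split between directions, with 646 higher and 219 lower genes. The count of changed genes dropped by more than 1.5 times when a library was left out, to 996, 678 and 807 without control library 1, 2 or 3, and to 848 and 723 without mimic library 1 or 3.

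**Figure D1:**
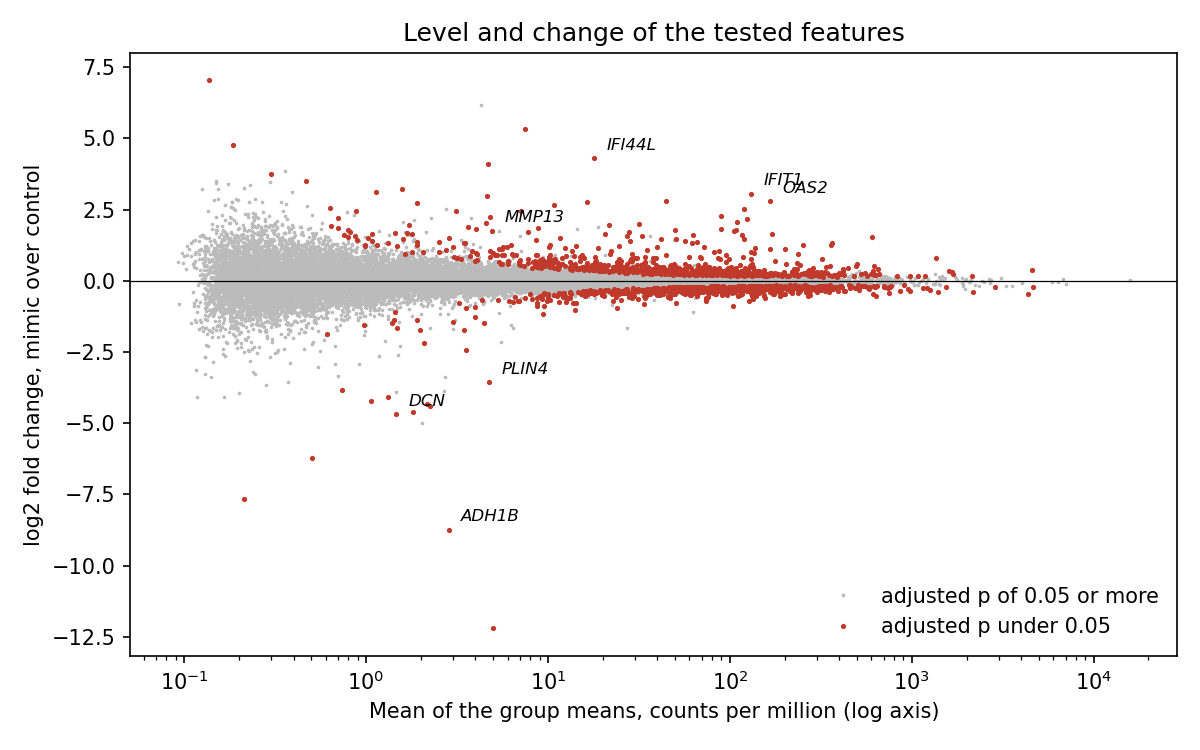
Each point is 1 of the 22086 tested features, placed by the mean of its group means in CPM (log axis) and by its log2 fold change, mimic over control. Red points passed an adjusted p of 0.05 and include 114 features higher and 28 lower by a log2 fold change of 1 or more, with IFI44L at 4.31 and MMP13 at 1.76.

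The largest rises among the named genes were mostly interferon-stimulated genes. IFI44L (ENSG00000137959; chromosome 1, 78619902 to 78646145) rose from 1.72 ± 0.813 to 34.2 ± 10.8 CPM, a log2 fold change of 4.31 (SE 0.31; adjusted p = 1.9e-05). Its neighbour IFI44 (chromosome 1, 78649796 to 78664078) rose by 2.81 (SE 0.14). OAS2 and OAS1, enzymes that sense double-stranded RNA and activate RNase L, lie close together on chromosome 12 (112978395 to 113011723 and 112905856 to 112933219). OAS2 rose from 42.0 ± 5.80 to 290 ± 29.1 CPM, and OAS1 from 36.0 ± 2.36 to 204 ± 27.7 CPM. Log2 fold changes were 2.79 (SE 0.10) for OAS2 and 2.51 (SE 0.09) for OAS1, each with an adjusted p of 2.3e-07. Log2 rises were also measured for MX2, an antiviral GTPase, at 2.76 (SE 0.18), XAF1 at 2.65 (SE 0.16) and OAS3 at 1.33 (SE 0.05). RSAD2 rose by 2.99 (SE 0.35) at a lower level, and CMPK2, which overlaps it on the opposite strand, rose by 3.22 (SE 0.46). IFIT1 (chromosome 10, 89392546 to 89406487) overlaps LIPA on the opposite strand, which rose by 0.59 (SE 0.06). The kit and the counting are not stated to keep strand, so reads from stretches that such pairs share cannot be told apart. Overlap was taken from gene spans, and shared exons were not checked. CXCL10 (1.90), CXCL11 (1.06) and IRF7 (-0.09) did not pass, at adjusted p of 0.10, 0.47 and 0.94. Camera gave the list an adjusted p of 1.4e-43 with a preset correlation of 0.01 and of 0.14 with an estimated correlation. Adjusted over the list alone, 36 members rose.

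**Figure D2:**
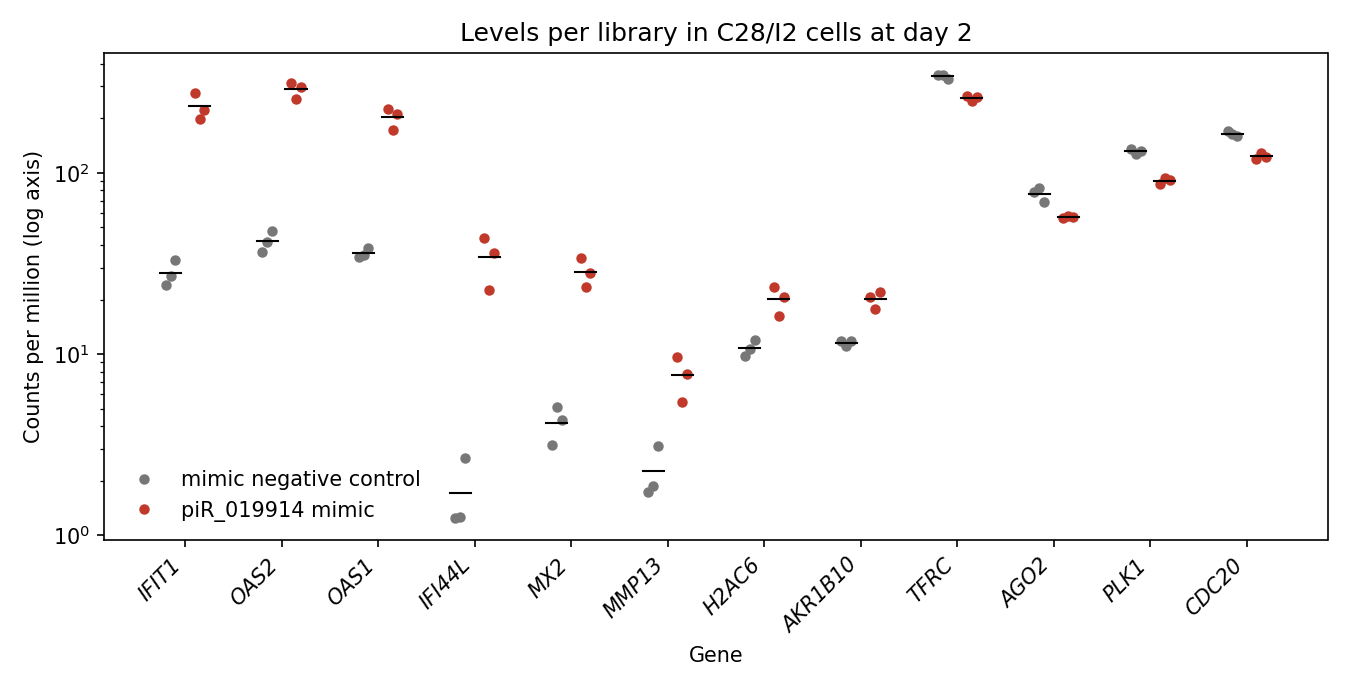
Levels in CPM (log axis) of 12 genes in each of the 6 libraries, with control libraries in grey, mimic libraries in red and the mean of each group of 3 as a line. All 3 mimic libraries lie above all 3 control libraries for the genes from IFIT1 to AKR1B10 and below them for TFRC, AGO2, PLK1 and CDC20.

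Cell division genes moved the other way. PLK1, a kinase that drives entry into and passage through mitosis, fell from 131 ± 4.73 to 90.6 ± 4.02 CPM (log2 fold change -0.54, SE 0.05; adjusted p = 1.7e-04). CDC20, which activates the anaphase-promoting complex, was lower by -0.41 (SE 0.05), the kinetochore gene CENPF by -0.37 (SE 0.05) and BIRC5 by -0.33 (SE 0.05). In the mitosis and G2/M list none of the 34 tested members rose and 14 did not pass. Camera gave an adjusted p of 7.7e-13, and 0.10 with an estimated correlation. Adjusted over the list alone, 29 members fell. In the DNA replication and G1/S list 7 of 33 tested members fell, 26 did not pass and the median was -0.08 (camera adjusted p = 2.5e-04; 11 fell adjusted over the list alone). The adjusted p was 0.31 with an estimated correlation. E2F1, a transcription factor of the G1/S transition, fell by 0.42 on the log2 scale (SE 0.08), and the replication helicase gene MCM5 fell by 0.27 (SE 0.05), a call that ended without mimic library 3 (adjusted p = 0.055). Replication-dependent histone genes had a median log2 fold change of 0.59, with 4 of 20 tested members risen (also 4 adjusted over the list alone) and 16 not past the test. Among them H2AC6 rose by 0.91 (SE 0.14), H1-2 by 0.71 (SE 0.12) and H2BC12 by 0.67 (SE 0.11). The histone list had a camera adjusted p of 3.5e-05, and an adjusted p of 0.13 with an estimated correlation. Histone genes are near copies of one another, so their separate counts are uncertain.

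Lists of oxidative defence, hypoxia and sterol synthesis genes passed camera as higher with the preset correlation only, with small medians and most members not past the gene test. In the list of NRF2 targets, genes of antioxidant defence, 7 of 25 tested members rose and 18 did not pass, with a median of 0.11 (camera adjusted p = 4.4e-04, and adjusted p = 0.14 with an estimated correlation). AKR1B10, an aldo-keto reductase, rose from 11.6 ± 0.382 to 20.1 ± 2.10 CPM (log2 fold change 0.80, SE 0.10), and AKR1C1 rose by 0.57 (SE 0.09). Adjusted over the list alone, 11 rose and 1 fell. Hypoxia targets had 5 of 23 tested members risen and 18 not past the test, with a median of 0.17 (camera adjusted p = 2.5e-04; 10 rose adjusted over the list alone). Its adjusted p was 0.31 with an estimated correlation. P4HA1, a collagen prolyl hydroxylase subunit, rose by 0.48 (SE 0.05), EGLN3, an oxygen-sensing hydroxylase, by 0.39 (SE 0.05), and NDRG1 by 0.37 (SE 0.06). In the cholesterol biosynthesis list 9 of 25 tested members rose, 16 did not pass and the median was 0.09, or 0.15 without control library 3 (camera adjusted p = 0.0013; 12 rose adjusted over the list alone). An estimated correlation gave an adjusted p = 0.31. The sterol enzyme genes MSMO1, SC5D and FDFT1 rose by 0.45 (SE 0.05), 0.37 (SE 0.06) and 0.28 (SE 0.04), and INSIG1, a sterol sensor that restrains the pathway, by 0.38 (SE 0.05).

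Inflammatory and YAP/TAZ target genes also passed the list test, as higher and as lower. In the NF-kappaB list the neutrophil chemokine CXCL8 was the single member that rose, from 38.9 ± 1.34 to 50.7 ± 3.49 CPM, while 26 of 27 did not pass and the median was 0.26 (camera adjusted p = 0.0030, and adjusted p = 0.31 with an estimated correlation). Also 1 rose when adjusted over the list alone. IL1B stood at a log2 fold change of 1.38 (SE 0.43; adjusted p = 0.090). Of 25 tested YAP/TAZ targets, 7 fell, 1 rose and 17 did not pass, with a median of -0.14 (camera adjusted p = 0.0077; 10 fell and 2 rose adjusted over the list alone). The adjusted p was 0.31 with an estimated correlation, and 0.10 after an offset for GC content and length. PTPN14 and AXL were lower by -0.47 (SE 0.06) and -0.37 (SE 0.04), and NT5E was higher by 0.40 (SE 0.04).

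The other 6 lists past the camera threshold lost the call when single libraries were left out. Matrix-degrading enzymes had a median of 0.08 (0.049 without control library 1, 0.14 without control library 3 and 0.12 without mimic library 1), with 4 of 23 tested members risen and 19 not past the test (adjusted p = 0.016, and 0.48 with an estimated correlation). Secreted factors of senescent cells had a median of 0.16, with 3 of 25 risen and 1 fallen (adjusted p = 0.022, and 0.48 with an estimated correlation). Mitochondrially encoded mRNAs had a median of -0.11 (-0.20 without control library 3, -0.028 without mimic library 1 and -0.21 without mimic library 2), with 3 of 13 fallen, among them MT-ND6 (-0.53, SE 0.10). That list's adjusted p was 0.023, and 0.67 with an estimated correlation. Apoptosis regulators had 6 of 32 risen, among them BMF (0.56, SE 0.10), a pro-apoptotic BCL2 family gene (median 0.11; adjusted p = 0.032, and 0.40 with an estimated correlation). Ferroptosis suppressors had 2 of 23 risen (median 0.10; adjusted p = 0.035, and 0.31 with an estimated correlation). Autophagy and lysosome genes had 7 of 34 risen, led by GABARAPL1 (0.41, SE 0.05; median 0.08; adjusted p = 0.038, and 0.31 with an estimated correlation). Adjusted over the list alone, 5, 6, 0, 7, 3 and 10 members of these lists rose and 0, 1, 4, 1, 0 and 2 fell, in the same order. Without control library 2 the adjusted p was 0.053, 0.11, 0.053, 0.072, 0.11 and 0.13 for these lists in turn. Leaving out control library 1 also ended the calls of matrix-degrading enzymes (0.30), senescence factors (0.12), mitochondrial mRNAs (0.13), ferroptosis suppressors (0.11) and autophagy genes (0.096). Leaving out control library 3 ended those of apoptosis (0.068) and autophagy genes (0.064). Without mimic library 1 the 6 lists stood at 0.059, 0.098, 0.31, 0.098, 0.10 and 0.096. Without mimic library 3 the matrix-degrading (0.062), senescence (0.063), apoptosis (0.072) and autophagy (0.087) lists did not pass, and the autophagy median was 0.054. The offset for GC content and length ended the calls of senescence factors (0.091), ferroptosis suppressors (0.21) and autophagy genes (0.086). Matrix-degrading enzymes (0.070), senescence factors (0.097) and mitochondrial mRNAs (0.37) did not pass fry.

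**Figure D3:**
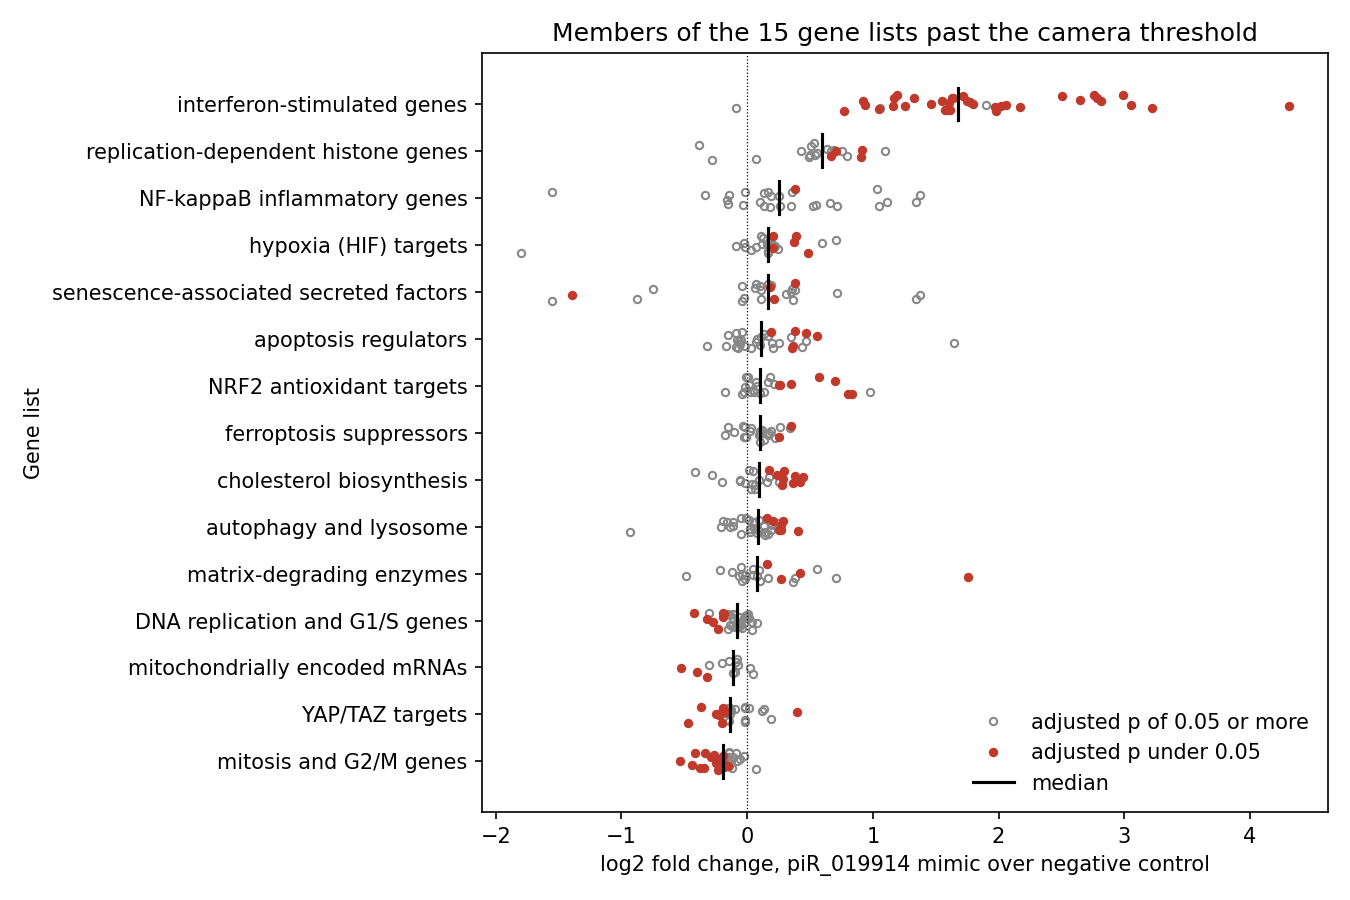
Log2 fold changes, mimic over control, of the tested members of the 15 lists past the camera threshold. Filled red points are members with an adjusted p under 0.05, open points the others, and the bar is the median of each list, from 1.68 for interferon-stimulated genes to -0.19 for mitosis and G2/M genes.

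The camera calls rest on the preset correlation. None of the 36 tested lists passed with an estimated correlation, where the smallest adjusted p was 0.10 and 5 lists had an unadjusted p under 0.05. Fry, a rotation test of whether a list moves on balance in one direction without comparing it with other genes, gave 12 lists under 0.05. Camera gave 9 lists without control library 2 and 9 without mimic library 1. Other splits of the same 6 libraries into 3 and 3 gave up to 10 lists past the preset camera threshold, against 15 for the real groups. Each of these splits mixes libraries of both groups, so their counts are no measure of chance calls.

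Cartilage genes did not pass camera as a list. COL2A1, the main collagen of hyaline cartilage, held counts in 1 control library only, at 0.067 CPM, and was not tested. ACAN, which encodes aggrecan, was at 12.5 ± 1.55 with the mimic and 14.5 ± 0.536 CPM with the control (adjusted p = 0.35), and SOX9, the transcription factor of the chondrocyte lineage, at 44.1 ± 1.36 and 38.3 ± 1.51 CPM (adjusted p = 0.083). In the cartilage list 1 of 20 tested members fell and none rose, also when adjusted over the list alone (median -0.16; camera adjusted p = 0.44). That gene was DCN, which encodes the small proteoglycan decorin, at 0.108 ± 0.0961 with the mimic and 2.82 ± 0.975 CPM with the control (log2 fold change -4.69, SE 0.67; adjusted p = 0.0024). MMP13, the collagenase that cuts type II collagen, rose 3.39-fold, from 2.25 ± 0.76 to 7.63 ± 2.13 CPM (adjusted p = 0.0037). MMP3, or stromelysin 1, was at 95.2 ± 4.31 and 85.0 ± 8.59 CPM (adjusted p = 0.22). ADAMTS5, an aggrecanase, lay at 0.067 and 0.26 CPM and was not tested.

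Among genes of iron handling and ferroptosis, the transferrin receptor TFRC fell from 341 ± 9.80 to 259 ± 9.13 CPM (log2 fold change -0.40, SE 0.04; adjusted p = 4.9e-04). GPX4, the lipid peroxide reductase, had a log2 fold change of 0.11 (SE 0.05; adjusted p = 0.24), SLC7A11, the cystine transporter subunit, of -0.03 (SE 0.06; 0.87), ACSL4 of 0.14 (SE 0.05; 0.14) and ferritin heavy chain FTH1 of 0.02 (SE 0.05; 0.87). Ferritin light chain FTL rose by 0.25 (SE 0.05; 0.012), a call that ended in 2 of the fits without a single library (adjusted p up to 0.072). Lactate dehydrogenase LDHA stood at 0.11 (SE 0.03; 0.090). Of the Argonaute genes AGO2, the slicer of small RNA silencing, fell from 76.4 ± 6.91 to 57.3 ± 0.786 CPM (log2 fold change -0.41, SE 0.07; adjusted p = 0.0047). AGO1 fell by 0.33 (SE 0.07), without control library 1 or 2 or mimic library 1 at an adjusted p of 0.054, 0.091 and 0.079. PIWIL4, a PIWI gene, was near 1 CPM in both groups (log2 fold change -0.48, SE 0.43; adjusted p = 0.62). TDRD7 and MOV10 rose by 0.55 (SE 0.07) and 0.48 (SE 0.05), so that in the small RNA machinery list 2 of 25 rose, 2 fell and 21 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.69).

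Further lists did not pass camera. Their adjusted p was 0.12 for proteasome subunits, 0.18 for hypertrophic chondrocyte markers, nuclear respiratory chain genes and the heat shock response, 0.21 for the unfolded protein response, 0.27 for ferroptosis drivers, 0.31 for glycolysis, 0.38 for reactive oxygen species enzymes, 0.40 for immediate early genes, 0.46 for fibroblast-type matrix genes and p53 targets, and 0.66 for ATF4 targets. It was 0.71 for cytosolic ribosomal proteins and fatty acid synthesis, 0.92 for the TGF-beta response and 0.93 for Wnt targets. The median of the oxygen species list was 0.05 and its mean -0.04. In the TGF-beta list 5 of 23 members rose, among them ID2 (0.62, SE 0.10), and 4 fell, among them THBS1 (-0.25, SE 0.04), and 7 rose and 6 fell adjusted over the list alone. In the glycolysis list PFKFB4 rose by 0.57 (SE 0.08). Single libraries decided some of these results. Without control library 1 the proteasome, nuclear respiratory chain and endothelial lists passed (0.023, 0.012 and 0.028), and so did the ribosomal proteins, as higher (0.043). The direction turned elsewhere, as ribosomal proteins passed camera as lower after the offset for GC content and length (4.9e-04). Their median was -0.14 without control libraries 2 and 3. Without mimic library 2 the proteasome and nuclear respiratory chain lists passed (0.029 each). After the offset for GC content and length the heat shock response passed as lower (0.0091) and hypertrophic chondrocyte markers as higher (0.035), and heat shock also passed without control libraries 2 and 3 (0.043). Markers of other cell types gave an adjusted p of 0.28 for epithelial, 0.29 for endothelial and 0.71 for leukocyte genes, where CD68 rose by 0.36 (SE 0.06), and fewer than 5 of the erythroid and liver markers could be tested.

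Several of the largest falls had limits of their own. ADH1B, an alcohol dehydrogenase abundant in liver and fat (chromosome 4, 99304971 to 99321401), had 2 counts over the 3 mimic libraries and 1030 over the 3 control libraries, 0.192% of the control level (95% exact binomial interval 0.0233 to 0.696%, counting error only, and too narrow if a fragment gave several counts). Control libraries 1, 2 and 3 held 0.754, 13.8 and 2.54 CPM of it. The share was 0.670% without control library 2 (interval 0.0805 to 2.45%), 0.289% and 0.291% without mimic library 1 or 3, and rested on 0 mimic counts without mimic library 2 (upper bound 0.528%). PLIN4, a lipid droplet protein, was at 0.744 ± 0.243 and 8.72 ± 7.06 CPM (log2 fold change -3.55, SE 0.73), and GPX3, a secreted peroxidase, at 2.33 ± 0.737 and 5.60 ± 2.61 CPM (-1.27, SE 0.33). Transcripts of fat cells stood out in the same control libraries. ADIPOQ, which encodes adiponectin, was at 10.3 and 6.89 CPM in control libraries 2 and 3 and had no counts in the other 4 libraries. PLIN1 and LPL lay at 7.67 and 5.97 CPM in control library 2, at 4.91 and 4.01 CPM in control library 3, and under 1 CPM elsewhere. The endothelial marker VWF was at 5.28 and 7.41 CPM in these libraries, against 1.60 CPM in control library 1, and passed without that library (adjusted p = 0.019). Without these 2 libraries, an alternative chosen after seeing the data, 238 genes passed, 170 higher and 68 lower, with the single control library assumed to vary like the mimic libraries. In that fit PLIN4 was at -0.43 (adjusted p = 0.80) and GPX3 at -0.55 (0.57). ADH1B did not pass (0.11), although its fitted log2 fold change was still -5.81, 0.665 of that with all libraries. DCN passed (0.046). The PLIN4 call also ended without control library 2 (0.071) or 3 (0.058) and mimic library 1 (0.063) or 3 (0.089). The GPX3 call ended without control library 2 (0.19) or 3 (0.093) and mimic library 2 (0.13) or 3 (0.16).

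**Figure D4:**
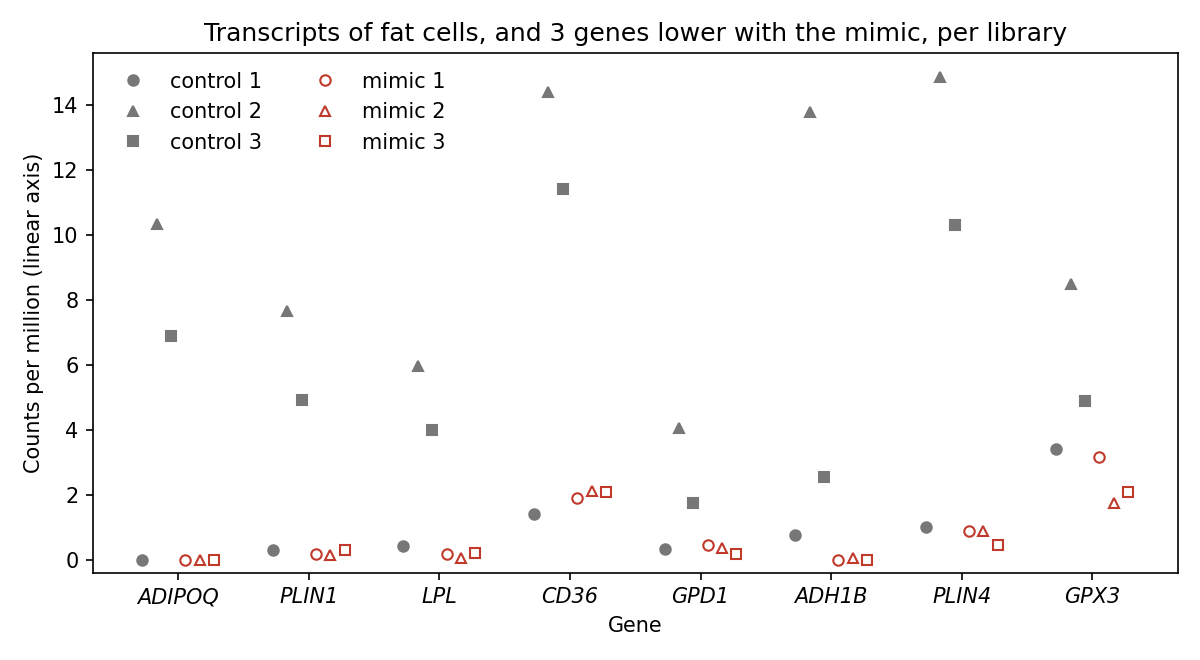
CPM (linear axis) in each library of 5 transcripts of fat cells and of ADH1B, PLIN4 and GPX3, with filled grey marks for control and open red marks for mimic libraries. ADIPOQ lies at 10.3 and 6.89 CPM in control libraries 2 and 3 and at 0 in the other 4.

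Some other leading changes were in overlapping or repeated gene models. PTGES3L-AARSD1, a read-through transcript on chromosome 17 (42950526 to 42980528), rose from 0.514 ± 0.451 to 8.87 ± 0.983 CPM, while AARSD1, with which it shares exons, fell from 18.8 ± 1.49 to 9.33 ± 2.07 CPM. Their sum was 18.2 ± 1.14 CPM with the mimic and 19.3 ± 1.48 CPM with the control. TVP23C-CDRT4, another read-through, was lower by -1.18 (SE 0.22), while TVP23C stood at 0.16 (adjusted p = 0.68) and CDRT4 at 1.76 (0.32). PCDHGB7 (-0.96, SE 0.15) belongs to the protocadherin gamma cluster, whose genes share exons. POTEM (2.47, SE 0.19) has near-identical relatives in the genome. Counts of these models depend on how shared reads were divided. Among the remaining leading falls, SOGA1 (chromosome 20, 36777447 to 36863538) fell from 135 ± 2.46 to 73.8 ± 7.23 CPM (log2 fold change -0.87, SE 0.07; adjusted p = 2.5e-05). The noncoding transcripts TRIM8-DT and LINC01963 were lower by -1.48 (SE 0.23) and -0.87 (SE 0.15), and FBXL6 by -0.88 (SE 0.17; adjusted p = 0.050 without control library 1). In all, 39 changed features had no gene symbol and are counted but not named.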

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

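Tests chosen only after the data were seen were limma on log2 CPM, the GC and length offset and the counts divided by 4. The fit without control libraries 2 and 3 was also chosen then. Limma on log2(FPKM + 1) had been named in the fixed design for a table without raw counts. The main counts of 1557 changed, 711 higher and 846 lower genes moved by over 1.5 times under the settings that follow. DESeq2 gave 2484, 1093 and 1391 genes, and 1537 of the main calls were among them. No low-count filter gave 777, 401 and 376, limma without a trend 96, 81 and 15, an absolute log2 fold change of 1 or more 142, 114 and 28, and an adjusted p under 0.1 gave 2465, 1112 and 1353. Limma on log2(FPKM + 1) gave 865 changed and 219 lower genes, with 715 of the main calls among the 865. With pseudocounts of 0.1 and 0.01 the counts were 840 and 213, and 830 and 212. Leaving out 1 library gave 678 to 1575 changed, 330 to 665 higher and 348 to 910 lower genes and 9 to 17 lists. Leaving out control libraries 2 and 3 gave 238, 170 and 68, where fewer control libraries enter. For the others, except where fewer features or libraries or another threshold set the count, the cause was not tested. The 15 changed lists became 0 with an estimated correlation. Of the 15 lists, 8 kept the call in every setting with the preset correlation and 9 did so without each library in turn. Cytosolic ribosomal proteins, not called in the main test (median -0.015), had medians of -0.0643 to 0.0691 without 1 library, passed as higher without control library 1 (0.0691), and passed as lower with the GC and length offset (-0.075) and without control libraries 2 and 3 (-0.14). Among other lists not called in the main test, the GC and length offset gave heat shock (-0.080, adjusted p = 0.0091) and hypertrophic chondrocyte markers (0.20, 0.035), and limma on log2(FPKM + 1) gave nuclear respiratory chain (0.025), proteasome (0.022) and reactive oxygen species genes (0.046), as did the other pseudocounts. Limma on quantile-normalized values also gave nuclear respiratory chain (0.031) and proteasome genes (0.016), and library weights gave proteasome genes (0.049). Of 117 named genes past the threshold, none changed sign under any setting, 66 stayed past it without each library in turn, and 106 lost the call under at least 1 setting. Limma without a trend by itself ended 106 of the calls. With the replicate number as a block, 1436 genes changed (650 higher, 786 lower) and 12 lists, without apoptosis regulators, autophagy and ferroptosis suppressors. Libraries with the same number did not deviate together (correlations of deviations 0.04, -0.01 and 0.01), and 2 of 3 correlated best with their own number, so the numbers were not read as pairs. Depth and spread limit the detection of small changes. In features with a mean of 5 CPM or more, 57 of 100 simulated changes of 0.5 log2 were found and 92 of 100 of 1 log2. Lower levels were not simulated.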

Other observations

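Among the tests below, the one that leaves out single libraries, both tests of a response to the transfected RNA, the ranking of libraries by fat cell transcripts, the control levels of ADH1B, PLIN4 and GPX3, and the test of GO terms were chosen only after the result was seen. Of 2584 GO terms given in the table, 26 passed camera with the preset correlation as higher and 42 as lower, and none with an estimated correlation, where 112 had an unadjusted p under 0.05. Besides antiviral terms, the higher ones included NAD+ ADP-ribosyltransferase activity, with 7 of 22 members risen and none fallen (median log2 fold change 0.10). PARP9 and PARP14, ADP-ribosyltransferases of the antiviral response, rose by 1.62 and 1.16, and were chosen after their values were seen. Lower terms included mitotic ones, such as mitotic spindle organization, with 18 of 57 members fallen and 1 risen (median -0.14). They also included ribosomal large subunit assembly, with 6 of 22 fallen and none risen (median -0.14), and ribosome biogenesis, with 9 of 101 fallen and none risen (-0.06). Camera with an estimated correlation gave an unadjusted p of 0.028 for the spindle term, and of 0.17 and 0.23 for the ribosomal terms.

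The interferon list had a median log2 fold change of 1.68. A trend with GC content or length as the whole cause is argued against by the offset, after which the median was 1.64 and 38 of 38 members were above 0. A single library is argued against by the medians without each of the 6 libraries, the lowest of which was 1.57. A response equal for any transfected RNA would leave the groups level, as both received RNA. The median of 1.68 argues against it as the whole cause. That value is the pattern itself, so it adds no separate evidence. It does not bear on a response to RNA that differs in strength between the mimics. A response to the RNA preparation (amount, purity or structure) and an effect of what the piR_019914 sequence targets cannot be told apart. Labels of the libraries analysed name only the piR_019914 mimic and its negative control, and no further RNA or separate preparation of the mimic. The sequence-specific effect that the design names stays untested as a hypothesis.

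A candidate source of the ADH1B, PLIN4 and GPX3 signal is RNA from fat tissue in control libraries 2 and 3. Of 26 listed fat cell transcripts with counts, chosen without ADH1B, PLIN4 and GPX3, 19 had these as their 2 highest libraries. ADIPOQ was at 10.3 and 6.89 CPM in them, CD36 at 14.4 and 11.4 CPM and FABP4 at 4.30 and 2.05 CPM. A chance count of 1.73 holds only for a pair of libraries fixed beforehand and transcripts that vary independently. The pair was chosen after the result was seen and the transcripts may vary together, so 1.73 is no measure of chance here. The sum of the listed transcripts was 147 and 123 CPM in control libraries 2 and 3 and 74.8 to 82.1 CPM in the other 4 libraries. The sum in control library 2 was 1.82 times that in the highest mimic library, between the bounds of 1.5 and 3 set beforehand. Of the transcripts, 7 were above 1 CPM in each of those 4 libraries. Much of each sum came from PNPLA2, DGAT2 and C7. They lay at 37.6, 21.2 and 14.2 CPM in control library 2 and at 26.7, 23.5 and 13.5 CPM in mimic library 1. The ratio of sums therefore says little about the other listed transcripts. A fall within the transfected cells stays open for all 3 genes. The highest control library held 18.3, 14.8 and 2.49 times the lowest for ADH1B, PLIN4 and GPX3, but a spread between single libraries does not decide this. Without control libraries 2 and 3, 0.665, 0.122 and 0.434 of the fitted log2 fold changes were left, against 1 control library. ADH1B was 5.43 times higher in control library 2 than in 3, where ADIPOQ was 1.5 times and PLIN4 1.44 times higher.

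Words of 7 bases in the 3' UTR were searched, as possible sites of a small RNA guided by a seed. For each word, the rank of the log2 fold change was compared between genes with and without it. UTR length, GC content and expression level were fitted alongside. The scan covered 11066 genes, whichever way they moved, and did not use the called lower genes as a set. Of 15560 words 14 passed Bonferroni towards lower genes, led by TATTTTT, which 47.7% of the genes hold. The mean log2 fold change was -0.0041 in genes with that word and 0.013 in genes without it. Within bins of GC content and 3' UTR length its holders were lower by a log2 difference of -0.033 (permutation p = 0.0001, the smallest that 10000 permutations can give). The word had been picked as the leading one on the same genes, so that p does not decide on a GC or length trend, which stays open. Whether the words reflect seed-like sites is open too. A single seed would give overlapping words, but the largest set of the leading 10 words joined by overlaps of 6 bases held 2 words, 3 words held no G or C and 7 held 6 or more. No sequence of the mimic was used here.

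With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1557 changed genes and the highest of the others 2, so only the real split itself reached its count. Each other split mixes libraries of both groups, so the group difference adds to the spread within it. Its counts are therefore no measure of what chance gives. For changed lists the real split gave 15 and the highest of the others 10, and again only the real split reached its count.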
